A study of Homo sapiens with 4 samples.

How the data were processed

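A massively parallel reporter assay was run in BEAS-2B cells, an established human bronchial epithelial cell line, on variants of the FAM13A locus on chromosome 4 that genome-wide studies have tied to chronic obstructive pulmonary disease. Per the labels, oligonucleotides were made on an Agilent 244K array and cloned into a reporter plasmid with either a minimal promoter (minP), described as weak, or the simian virus 40 promoter (SV40), described as strong. The plasmid pools were amplified by PCR and sequenced as input. The cells were transfected by nucleofection and harvested 24 hours later, and reporter mRNA was reverse transcribed, amplified by PCR and sequenced with single reads of 36 nt. There were 4 libraries, 1 each of minP input, minP RNA, SV40 input and SV40 RNA, and no replicate transfection.

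The deposited table held whole-number read counts per tag for the 4 libraries, and each tag was an 11-base barcode of 1 oligonucleotide. It listed 218526 tags of 7270 oligonucleotides, with a median of 31 tags per oligonucleotide and a range of 4 to 33. The 606 variants had 2 alleles each and lay in 3 windows, named L, C and R, and in 2 orientations, named F and RC. What the window letters stand for was not given in the sources used here, nor was the way reads were matched to tags, filtered or deduplicated. No molecular identifiers were stated, so reads were not taken as independent molecules. Of the oligonucleotides, 394 from 51 variants carried a mark in their names whose meaning was not given, and they were kept. Positions are those of the table, whose genome build was not given in the sources used here. None was converted, and 0 of the 606 positions fell inside FAM13A in the gene table of assembly GRCh38.p14, so exon and intron positions were not analysed here and no converted coordinate is printed.

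The counts were used as deposited. For each tag with at least 10 input reads, the tag ratio was the log2 of the RNA count plus 1, divided by the RNA library total, minus the log2 of the input count plus 1, divided by the input library total. A construct is 1 variant in 1 window and 1 orientation, and its allelic difference was the mean tag ratio of the alphabetically later allele minus that of the earlier, because the table did not say which allele is the reference. At least 10 tags per allele were required. Allele names were permuted over the tags of a construct in a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05, and p-values were adjusted by Benjamini-Hochberg over the constructs of a library at 0.05. The unit of these tests is the tag within 1 transfection, so p-values measure the spread between tags and not between transfections. Count models such as those for replicate libraries were not used, because each group had 1 library.

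An element is 1 allele of a construct. Its activity was the mean tag ratio minus the mean over all tags of the library, tested two-sided against as many tags drawn at random from the library, with 100000 draws and the same adjustment. The table named no control elements, so the planned comparison with controls was not run, and higher or lower means relative to the average tag. The mean log2 tag ratio was -0.78 with minP and -1.01 with SV40, below the medians of -0.55 and -0.66, so an element at the median tag lies slightly above this reference. The difference of the allelic difference between the libraries was tested by permuting allele names over the per-tag difference of minP minus SV40, which with 1 library per group compares the libraries and not the promoters. The same difference of element activity was tested by flipping the signs of that difference after centring each library on its median. Correlations across constructs or elements had permutation p-values, adjusted over the 4 correlations computed between the promoters, and neither constructs nor elements are independent replicates. Read depths per library are given with the results, and no intervals between transfections could be had.

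Constructs were named by a rule fixed before the data were examined: per library up to 10 variants with the largest positive and 10 with the largest negative allelic difference past the threshold, up to 10 past it in both libraries, up to 5 with the largest promoter difference, and the 10 highest and 10 lowest elements. A list of 8 variants known from association studies of lung function, chronic obstructive pulmonary disease or lung fibrosis, or from this study itself, was fixed at the same time. Planned groups were transitions against transversions, that list against the other variants, substitutions against insertions and deletions, which could not be compared because all 606 variants were single-base substitutions, and position relative to the gene, which was not analysed here.

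Alternatives fixed beforehand were input minimums of 1 and 50, a pseudocount of 0.5, tags with 0 RNA reads left out, tags trimmed by 10% at each end, a rank statistic, summed counts, at least 30 tags per allele, tags passing in both libraries, and a random split of the tags into 2 equal parts. Tags were trimmed within each allele of a construct before the tests, which narrows their spread. The p-values with trimming are therefore too small, and the numbers passing too high. Tests of the mean of and the difference between the 2 orientations, RNA or input counts alone, the same or disjoint parts of the tags over 20 splits with at least 5 tags on each side, and tags beginning with TC left out were chosen after the data were seen. So was a test of the RNA and input parts of the difference between orientations, in which windows were chosen in 1 part of the tags and measured in the other. The allelic tests were tried on simulated data with allele names shuffled and log2 changes of 1 or 2 put into 200 constructs. For element activity, tag ratios were shuffled over all tags of a library and such changes added to 200 elements. For the promoter difference of elements, signs of the per-tag differences were flipped at random, which builds in the symmetry that its test assumes. For the allelic difference with minP, 13 of 100 changes of log2 1 and 52 of 100 changes of log2 2 were recovered among 3480 constructs, with 4 unchanged constructs called. With SV40, 9 of 100 and 43 of 100 were recovered among 3456 constructs, with 1 unchanged construct called. For the promoter difference of the allelic difference, 31 of 93 and 69 of 98 were recovered among 3309 constructs, with 8 unchanged constructs called. For element activity, 22 of 95 and 92 of 96 were recovered among 7006 elements with minP, with 4 unchanged elements called. With SV40 it was 16 of 95 and 78 of 95 among 6962 elements, with 5 unchanged elements called. For the promoter difference of element activity, 56 of 93 and 83 of 91 were recovered among 6688 elements, with 6 unchanged elements called. The computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.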

Results

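The data comprised tag counts from 4 sequencing libraries of a reporter assay that asked which of 606 single-base variants of the FAM13A locus alter reporter expression in bronchial epithelial cells, and whether this depends on the promoter. Variants lay between positions 89528529 and 90116697 of chromosome 4. Each of the 4 groups, minP input, minP RNA, SV40 input and SV40 RNA, held 1 library, so no value below has an error between transfections, and errors are standard errors over tags.

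The minP input library held 29398765 reads and the minP RNA library 11086933, with medians of 85 and 23 reads per tag. The SV40 input library held 26557676 reads and the SV40 RNA library 24504694, with medians of 76 and 50. With minP, 195477 tags had at least 10 input reads, and 26675 of them had 0 RNA reads. With SV40, 192818 tags passed and 16165 of them had 0 RNA reads. The typical allele had 29 passing tags, and the median SE of an allelic difference was 0.48 with minP and 0.53 with SV40 on the log2 scale. Small allelic differences were therefore not detectable at this depth, and many large ones would be missed too. In the simulated data only 52 of 100 changes of log2 2 were recovered with minP and 43 of 100 with SV40.

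With the minimal promoter, allelic differences were tested to ask which variants change enhancer activity. The largest belonged to rs10516821 at position 89727979, where the C allele was 11.1-fold higher than the T allele in window R, orientation RC (T minus C -3.47 ± 0.23 on the log2 scale, SE, 28 T and 33 C tags, permutation test, adjusted p = 0.00128). The same allele was 6.41-fold higher in window C of that orientation. For rs7672894 at 90077431, the T allele was 7.45-fold higher than A in window R, orientation F (2.90 ± 0.37, 30 and 31 tags). For rs62306390 at 90031328, the G allele was higher than A in all 3 windows of orientation F, by 2.48 ± 0.47, 2.74 ± 0.37 and 2.85 ± 0.27. In orientation RC of window L it was -1.25 ± 0.74. For rs10516821, window C in orientation F was 0.80 ± 0.65. The difference between orientations passed for both windows (adjusted p = 0.0083, permutation test chosen after the data were seen). In RNA counts alone that window of rs10516821 was -1.88 in orientation F and -2.41 in RC, and in input counts alone -2.67 and 0.27. For rs6857969 at 89986326, A was 8.35-fold higher than G in window C, orientation F, and G was 5.59-fold higher than A in window L, orientation RC. Input reads of the passing tags were 10166 for C and 12778 for T of rs10516821 in window R, orientation RC, and 365 for A and 3130 for G of rs6857969 in window C, orientation F. Among other called constructs they were 805 for A and 8489 for T of rs7672894 in window L, orientation RC, and 5700 for G and 699 for T of rs1513819 in window L, orientation RC.

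Of 3469 constructs tested with minP, 52 in 29 variants passed the threshold, 30 with the later allele higher and 22 with the earlier allele higher. Their median difference was 3.52-fold, with a range of 1.79 to 11.1. Others with a higher later allele by the naming rule were rs6828137 in window C, orientation F (T over G, 5.69-fold), rs2904163 in window C, orientation RC (G over A, 5.14-fold), rs1513819 in window L, orientation RC (T over G, 4.90-fold), rs2276936 in window R, orientation F (C over A, 4.58-fold), rs3017913 (G over A, 4.21-fold), rs33998578 (T over C, 4.08-fold) and rs12647781 (T over A, 3.81-fold). Others with a higher earlier allele were rs7672894 in window L, orientation RC (A over T, 5.04-fold), rs7695177 (C over G, 4.91-fold), rs2167750 (C over T, 4.01-fold), rs2013701 (G over T, 3.62-fold), rs7671167 in window L, orientation RC (C over T, 3.60-fold), rs1513819 in window L, orientation F (G over T, 3.06-fold), rs2178586 (C over T, 2.88-fold) and rs72882940 (A over G, 2.79-fold). The other windows of the same variant and orientation had the same sign in 87 of 98 cases. Of the 41 called constructs whose opposite orientation was tested in the same window, 36 had the opposite sign there. An unadjusted p under 0.05 was found for 258 constructs, or 7.44%. Of the 52, 16 passed in RNA counts alone, in either direction, and 21 in input counts alone, and 8 had the opposite sign in RNA counts alone. Among the named constructs these were rs7672894 in window L, orientation RC (0.89 in RNA alone), rs1513819 in window L, orientation RC (-0.17), rs2276936 (-0.023), rs72882940 (0.48) and rs7671167 in window L, orientation F, which passed in both libraries (1.93 in the ratio and -1.40 in RNA alone, adjusted p = 0.0362, permutation test). With trimmed tags 111 constructs passed, 28 with at least 30 tags per allele, and 139 in input counts alone, while 0 windows passed when their 2 orientations were averaged (permutation test, 101 of 1661 with an unadjusted p under 0.05). Of the named constructs, rs2178586, rs12647781, rs33998578, rs72882940, rs2167750 in window C, orientation F, and rs7671167 in window L, orientation RC, fell short of the threshold in at least 1 alternative. Splits of the tags and RNA or input counts alone were not counted here, and further named constructs fell short in RNA counts alone.

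With the SV40 promoter the same question was asked against a strong promoter. The C allele of rs10516821 was 9.44-fold higher than T in window C, orientation RC (-3.24 ± 0.39, 32 T and 30 C tags, permutation test, adjusted p = 0.00191). For rs2904163 at 89647069, the G allele was 7.64-fold higher than A in window L, orientation RC (2.93 ± 0.32, 31 and 32 tags). For rs7671167 at 89883979, the T allele was 7.50-fold higher than C in window L, orientation F (2.91 ± 0.31, 17 T and 32 C tags), while C was 5.46-fold higher than T in orientation RC of that window (-2.45 ± 0.49). In orientation F the passing tags of the T allele of rs7671167 held 621 input reads against 12116 for C, and 4073 RNA reads against 13462. In RNA counts alone T minus C in that construct was -0.63 with SV40 (adjusted p = 0.586) and -1.40 with minP (adjusted p = 0.0362, permutation tests), the opposite direction, and in input counts alone -3.54 and -3.33.

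Of 3439 constructs tested with SV40, 36 in 24 variants passed, 22 with the later allele higher and 14 with the earlier allele higher, with a median of 3.97-fold. The named constructs with a higher later allele further included rs1513819 in window L, orientation RC (6.91-fold), rs62306390 in window R, orientation F (6.72-fold), rs7672894 in window R, orientation F (6.14-fold), rs2276936 (5.12-fold), rs12647781 (4.66-fold), rs6857969 in window L, orientation RC (4.57-fold), rs2167750 in window C, orientation F (4.51-fold) and rs12643428 (T allele, 4.27-fold). Those with a higher earlier allele further included rs7672894 in window L, orientation RC (6.32-fold), rs7695177 (5.44-fold), rs13124775 (A allele, 4.21-fold), rs2178586 (3.40-fold), rs2013701 (3.33-fold), rs12645124 (A allele, 3.32-fold), rs2167750 in window L, orientation RC (3.28-fold) and rs1513819 in window L, orientation F (2.63-fold). An unadjusted p under 0.05 was found for 256 constructs. Of the 36, 22 passed in RNA counts alone and 14 in input counts alone, and 2 had the opposite sign in RNA counts alone, rs7671167 in window L, orientation F, and rs7672894 in window L, orientation RC (0.55 in RNA alone). The opposite orientation had the opposite sign in 17 of 24 called constructs. With trimmed tags 95 constructs passed, 61 with summed counts, 114 in input counts alone and 21 with at least 30 tags per allele, and 5 windows passed when their 2 orientations were averaged. Of the named constructs, rs12643428, rs12645124 in orientation F, rs13124775, rs2178586 and rs2904163 in window C fell short of the threshold in at least 1 alternative. Splits of the tags and RNA or input counts alone were again not counted, and further named constructs fell short in RNA counts alone.

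**Figure D1:**
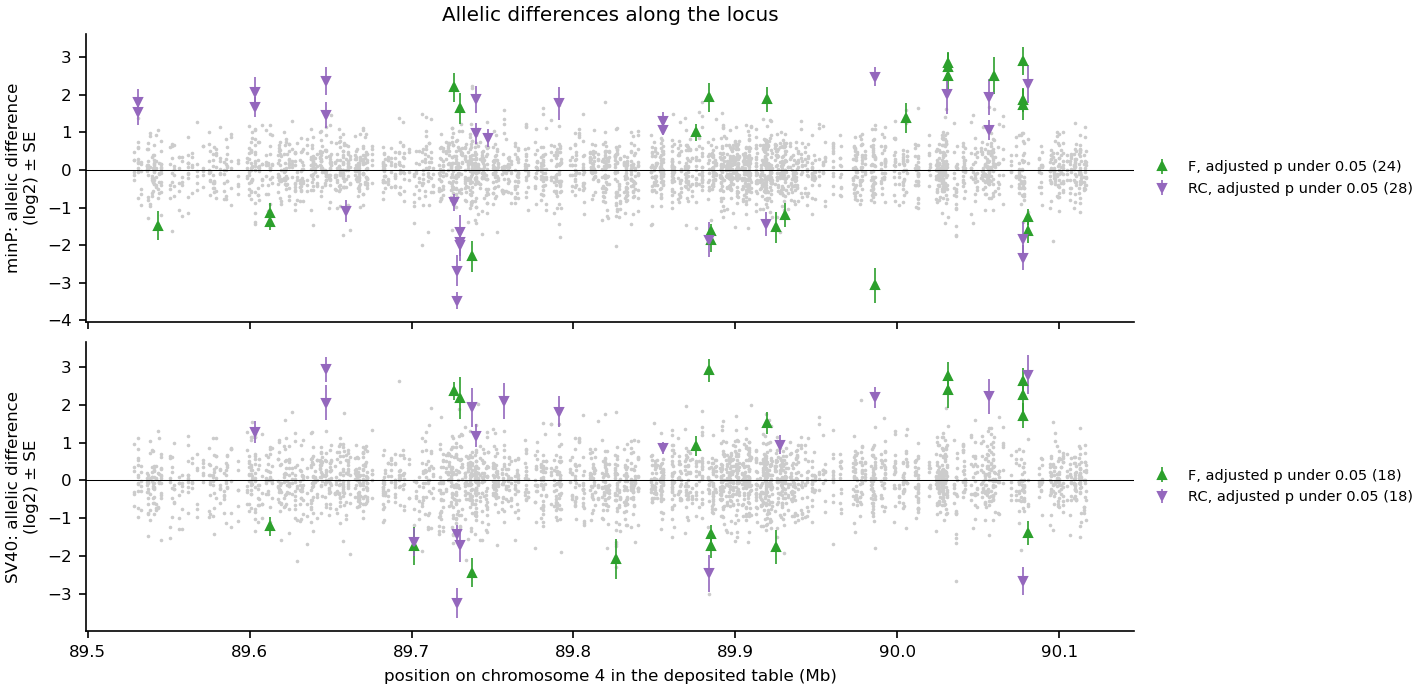
Allelic differences (log2, alphabetically later minus earlier allele) against position on chromosome 4 for minP above and SV40 below. Grey points are constructs that did not pass, and triangles with SE over tags are the 52 and 36 constructs that did, by orientation.

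Across both plasmid libraries, 29 constructs of 19 variants passed with the same sign, 18 with the later allele higher and 11 with the earlier, and 0 with opposite signs. By variant, the largest mean differences were those of rs10516821 in window C (C allele, 7.78-fold), rs62306390 in window R (G allele, 6.97-fold), rs7672894 in window R (T allele, 6.76-fold), rs1513819 in window L, orientation RC (T allele, 5.82-fold), rs7671167 in window L, orientation F (T allele, 5.35-fold), rs7695177 (C allele, 5.17-fold), rs6857969 (G allele, 5.05-fold), rs2276936 (C allele, 4.84-fold), rs2904163 (G allele, 4.62-fold) and rs12647781 (T allele, 4.21-fold). In RNA counts alone the direction turned for rs7671167 in both libraries (-1.40 with minP and -0.63 with SV40), and for rs1513819 (-0.17) and rs2276936 (-0.023) with minP, while it was 0.27 and 0.30 for the latter pair with SV40. Independent lists would share 0.193 and 0.0901 constructs in the 2 directions, and the highest overlap in 100000 permutations of construct names was 4 (p = 1e-05, the smallest they can give). Neither value, nor the p-values of the correlations between the libraries, takes account of the tags that both libraries share. Of the 23 constructs called with minP alone, 22 had the same direction with SV40, as did 7 of the 7 called with SV40 alone. Over all 3417 constructs, which are not independent, Pearson's r was 0.702 and Spearman's rho 0.678 (permutation p = 1e-05 for each and 1e-05 adjusted over 4 correlations, the smallest they can give). With trimmed tags 57 constructs passed in both libraries, and 17 with at least 30 tags per allele.

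The 2 libraries carried the same tags. When the tags were split at random into 2 disjoint parts, of the 24 constructs called with minP in the first part 23 were tested with SV40 in the other part, and 22 of these had the same direction. With the parts exchanged, it was 23 of 23. Constructs called with SV40 in 1 part had the same direction with minP in the other in 8 of 8 and 12 of 12 cases. Over all constructs, r between the promoters was 0.111 from disjoint parts and 0.690 from the same part, as means over 20 splits chosen after the data were seen. Within a library, r between disjoint parts was 0.134 with minP and 0.110 with SV40.

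**Figure D2:**
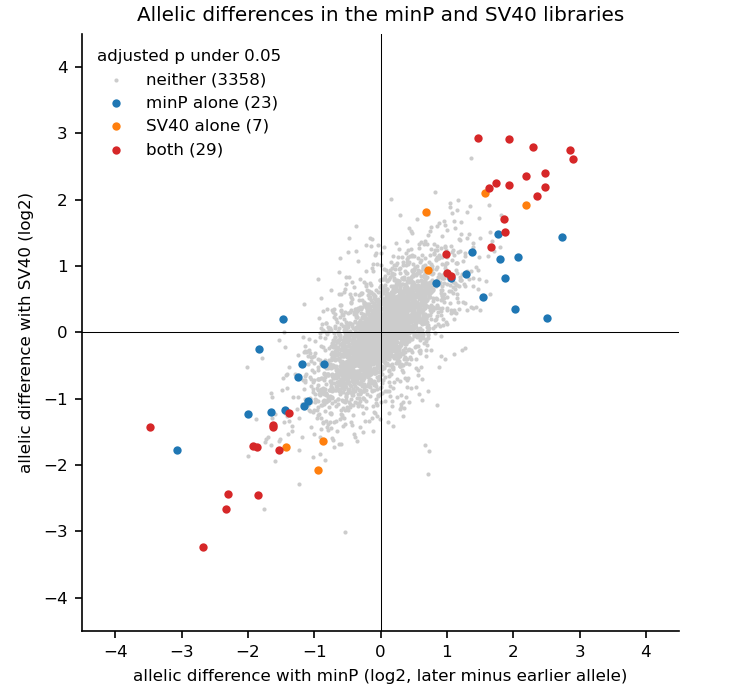
Allelic difference of each of 3417 constructs with minP (x axis, log2) and with SV40 (y axis, log2), coloured by the library in which the adjusted p was under 0.05. All 29 constructs called in both lie in the quadrants of equal sign.

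The allelic difference was compared between the promoters in 3278 constructs, and 2 passed. With 1 library per group the test compares these libraries and not the promoters. For rs10516821 in window R, orientation RC, the T minus C difference was -3.47 ± 0.23 with minP and -1.42 ± 0.23 with SV40, and the difference of minP minus SV40 was -2.06 ± 0.25 (27 T and 33 C tags, adjusted p = 0.0164, permutation test). For rs2904163 in window L, orientation RC, the G minus A difference was 1.47 ± 0.35 with minP and 2.93 ± 0.32 with SV40, a difference of -1.46 ± 0.25. In RNA counts alone rs10516821 stood at -3.00 with minP and -3.59 with SV40, a gap of the opposite sign, and in input counts alone at 0.47 and -2.17. For rs2904163 the values were 2.15 and 2.46 in RNA counts alone and 0.67 and -0.47 in input counts alone. An unadjusted p under 0.05 was found for 198 constructs, or 6.04%, while 11 constructs passed with summed counts, 6 without tags at 0 RNA reads and 5 with an input minimum of 50.

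Among the 8 listed variants, rs2013701 and rs7671167 passed in each library, with 4 constructs per library, including rs7671167 in window L, orientation F, whose direction was the opposite in RNA counts alone. The list includes variants known from this study, so its count is not independent evidence. For rs2013701 at position 89885086, the G allele was higher than T in orientation F in windows C and L, with T minus G differences of -1.86 ± 0.33 and -1.62 ± 0.19 with minP and -1.73 ± 0.31 and -1.42 ± 0.24 with SV40. In window R of that orientation the values were -1.33 ± 0.54 (adjusted p = 0.365) and -1.49 ± 0.57 (adjusted p = 0.424, permutation tests). The allelic difference of rs2013701 in orientation RC of window L was 0.40 ± 0.84 with minP and -0.015 ± 0.97 with SV40, with as few as 10 tags per allele. Adjusted over the list alone, 4 constructs of 2 variants passed with minP and 6 constructs of 3 variants with SV40, adding rs2869967 in window L, orientation RC (1.95 ± 0.57, adjusted p over the list alone = 0.0111, permutation test) and rs7671167 in window C, orientation RC (-3.01 ± 0.77, adjusted p over the list alone = 0.00966, permutation test). Over all constructs their adjusted p was 0.112 and 0.0881 (permutation tests). With trimmed tags it was 0.0150 and 0.0132 (permutation tests). Tags were trimmed within each allele, which narrows their spread and makes these p-values too small, so they lend no support. The listed rs1903003, rs6830970, rs2045517, rs4416442 and rs2609255 had no construct past either threshold.

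The list had 2 of 8 variants called with minP against 27 of 598 others (Fisher's exact test, two-sided, p = 0.0518) and 2 of 8 against 22 of 598 with SV40 (p = 0.0364), and neither passed adjustment over 8 tests (adjusted p = 0.207 for both). Transitions were called in 21 of 438 variants with minP and transversions in 8 of 168 (Fisher's exact test, p = 1). With SV40 the numbers were 17 of 438 and 7 of 168 (Fisher's exact test, p = 0.820). The median size of the allelic difference per variant was 0.32 for transitions and 0.35 for transversions with minP (permutation p = 0.0817, adjusted p = 0.218) and 0.36 and 0.37 with SV40 (permutation p = 0.439). For the list and the other variants it was 0.31 and 0.33 with minP (permutation p = 0.857) and 0.45 and 0.36 with SV40 (permutation p = 0.199).

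**Figure D3:**
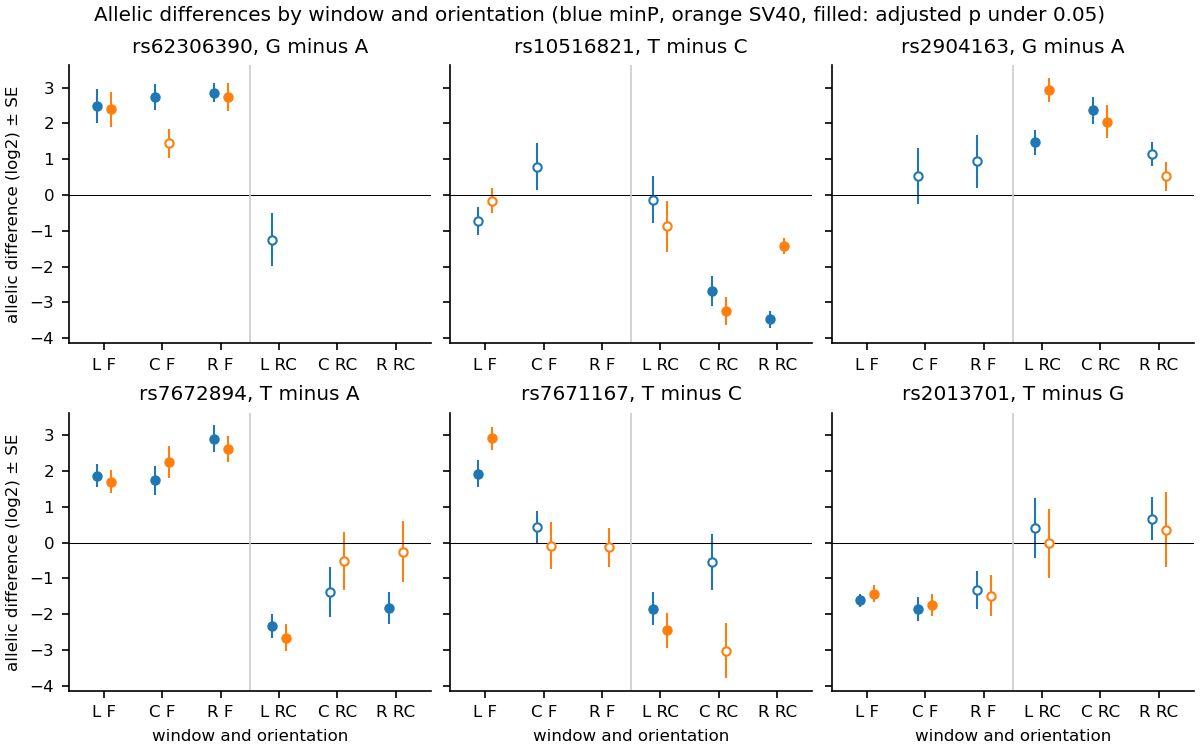
Allelic difference (log2, with SE over tags) of 6 variants by window (L, C, R) and orientation (F, RC), with minP in blue and SV40 in orange, and filled points where the adjusted p was under 0.05. For rs62306390 and rs2013701 the windows of orientation F share a sign, and for rs7672894 and rs7671167 window L has opposite signs in the 2 orientations. With minP, window L of rs62306390 and window C of rs10516821 also have opposite signs in the 2 orientations.

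Element activity was compared with the average tag to ask which sequences raise or lower expression. The highest elements with minP were rs7674369 at 89872176 in window R, orientation RC (G allele, 19.4-fold above the average tag, 4.28 ± 0.24, 20 tags), rs2869974 at 89937076 in window C, orientation F (C allele, 19.1-fold, 4.26 ± 0.23) and rs1398940 at 89937184 in window L, orientation F (A allele, 18.8-fold, 4.24 ± 0.28). With SV40 the highest were rs1398940 (G allele, 25.2-fold, 4.66 ± 0.26, 23 tags) and rs2869974 (C allele, 22.9-fold, 4.52 ± 0.22, 22 tags). Both alleles of rs2869974, rs1398940, rs10030965 and rs7674369 were among the 10 highest elements with minP, with rs10516826 (15.9-fold) and rs2924941 (15.1-fold) completing the list. With SV40 the list further held rs10030965 (A allele, 19.2-fold), rs7671167 in window L, orientation F (T allele, 16.1-fold), rs7674369 (15.8-fold), rs6814344 (15.0-fold) and rs2972021 (13.9-fold). The 10 highest elements averaged 15.8 to 31.5 input reads per tag with minP and 11.1 to 28.0 with SV40. Their RNA reads per tag averaged 75.3 to 138 with minP and 116.5 to 330 with SV40. Tags not beginning with TC averaged 137 input and 51.5 RNA reads with minP, and 123 and 114 with SV40. Input of these elements thus lay further below that average, in fold terms, than their RNA lay above it.

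Of 7006 elements with minP, 877 were higher and 1089 lower than the average tag, with median differences of 2.22-fold and 2.85-fold. Of 6962 with SV40, 950 were higher and 1238 lower, with medians of 2.45-fold and 3.05-fold. The lowest with minP were the G allele of rs6828137 in window C, orientation F (7.97-fold below), the G allele of rs7672716 (7.92-fold below), the A allele of rs1795734 (7.82-fold below) and the T allele of rs17014616 (6.86-fold below). The other 6, of rs2704577, rs60751124, rs76704358, rs62308744, rs1398946 and rs1903002, lay 6.16-fold to 6.46-fold below. With SV40 the lowest were the T alleles of rs73842243 (11.6-fold below), rs2125409 (10.9-fold below) and rs60107549 (10.4-fold below), followed by elements of rs62308744, rs2609264, rs6815970, rs10020704 and rs13138280 at 8.58-fold to 9.67-fold below. The 10 lowest elements of minP averaged 0.767 to 9.39 RNA reads per tag, and those of SV40 averaged 0.875 to 13.9. Input of the 10 lowest of minP averaged 32.2 to 206 reads per tag with minP and 12.8 to 59 with SV40, and was higher with minP for each. With SV40 these elements lay at -2.18 to -0.34 on the log2 scale. The 10 lowest of SV40 averaged 11.1 to 177 input reads with SV40 and 9.85 to 101 with minP, where they lay at -2.37 to -0.48. Their input was higher with SV40 except for rs62308744. With trimmed tags 1348 elements were higher with minP. Across elements, which are not independent, activity correlated between the 2 alleles (r = 0.814 with minP and 0.826 with SV40) while r between the 2 orientations was -0.125 and -0.0432.

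Element activity was compared between the promoters, with r = 0.908 and rho = 0.925 over 6926 elements (permutation p = 1e-05 for each and 1e-05 adjusted over 4 correlations, the smallest they can give). Both libraries carried the same tags, which these p-values do not take into account, and over 20 splits of the tags chosen after the data were seen mean r was 0.708 from disjoint parts and 0.875 from the same part. Within a library, mean r between disjoint parts was 0.743 with minP and 0.745 with SV40, little above the 0.708 between promoters. With all passing tags, 691 elements were higher in both libraries and 842 lower, with 0 in opposite directions. The difference between the libraries was tested on 6688 elements, and 142 passed, 55 with a higher ratio with minP and 87 with SV40. Among those named, rs73842243 (T allele, 2.79 ± 0.38 for minP minus SV40) and rs60107549 (T allele, 2.55 ± 0.42, A allele, 2.53 ± 0.44) had a higher ratio with minP, and rs6828137 (G allele, -2.56 ± 0.58) had a higher ratio with SV40, though its RNA part was 0.55, in the other direction, and its input part 3.11. The input counts contributed more than the RNA counts to 116 of the 142 differences, and 270 elements passed when tags with 0 RNA reads were left out, 234 with an input minimum of 1 and 88 with one of 50.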

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

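The tests on orientations, on split tags and on tags beginning with TC were chosen after the results they bear on had been seen, as were the RNA and input parts, and the tests of the difference between promoters were planned. The design names only the promoter and the kind of library as groups, so no biological explanation was tested for these patterns.

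The difference between the 2 orientations passed in 20 windows of 14 variants, 19 with minP and 7 with SV40, 6 of them in both libraries. The 2 estimates had opposite signs in all of them, but the test does not show that each differs from 0. In window L of rs7672894, rs7671167 and rs1513819 both orientations passed on their own in both libraries. With minP alone they also did in window R of rs7672894 (2.90 and -1.83), window C of rs2167750 (1.64 and -2.00) and window R of rs2276936 (2.19 and -0.86). For rs6857969 only 1 did, and window L with minP was -0.64 ± 0.80 in orientation F. The RNA and input parts had the same direction in all 26 pairs of a window and a library, which choosing windows by the ratio favours. Windows were therefore chosen anew in 1 part of the tags over 20 splits and measured in the other part. There input counts carried a share of 0.747 of the difference (95% interval over 190 variants 0.674 to 0.828). For windows chosen in this way, the value argues against RNA counts as the whole source, which would need a share of 0. It cannot decide on input counts as the whole source, because only tags with at least 10 input reads entered. Where an allele is scarce in input, its passing tags are those with the most input reads. Input and RNA counts correlate between tags of an element (r = 0.404 with minP and 0.388 with SV40), so the RNA part can then move too. Over all windows, r between orientations was -0.114 with minP and -0.063 with SV40 for the ratio, 0.184 and 0.180 in RNA counts alone, and 0.0200 and 0.133 in input counts alone. Of the 26 pairs of a window and a library in which the ratio was opposed, the signs were opposite in 17 in input counts alone and in 10 in RNA counts alone, and the source of either part stays open.

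The correlation of allelic differences between the promoters changed with the tags compared. Over 20 splits of 3293 to 3323 constructs, r was 0.111 from disjoint tags (range 0.0906 to 0.134) and 0.690 from the same tags (range 0.682 to 0.708). Within 1 library, disjoint tags gave 0.134 with minP and 0.110 with SV40. Allelic effects alone would give equal values for the same and disjoint tags, so the gap argues against them as the whole source, and yields of single tags shared by both libraries are a candidate source of most of the correlation over all constructs. Of constructs called with minP in 1 part, 22 of 23 and 23 of 23 had the same direction with SV40 in the other, 13 and 18 of them with an unadjusted p under 0.05 and 7 and 3 past the threshold. For those called with SV40 it was 8 of 8 and 12 of 12 with minP. Yields of single tags would not carry over to other tags, so these values argue against them as the whole source for called constructs. Whether the part tied to the allele lies in RNA or in input counts was not separated by the split.

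Tags beginning with TC, 3356 or 1.54% of all, had few reads in all 4 libraries. Their input reads per tag were 31.1-fold below other tags with minP and 32.9-fold below with SV40, and their RNA reads 11-fold (95% interval 9.97 to 12.2) and 10.8-fold (9.82 to 12) below. The fall in RNA argues against a loss in the input reads alone. The fall in input exceeded that in RNA by 2.83 times (2.5 to 3.18) with minP and 3.05 times (2.69 to 3.45) with SV40, which argues against loss of the plasmids alone. A mixture of these may remain. With such tags left out 52 and 36 constructs passed. Among tags with at least 10 input reads only 0.315% with minP and 0.261% with SV40 began with TC, so leaving them out could change little.

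The allelic difference differed between the minP and SV40 libraries, by a test over tags that compares these libraries and not the promoters, for rs10516821 in window R, orientation RC (-2.06 for minP minus SV40) and rs2904163 in window L, orientation RC (-1.46). In RNA counts alone rs10516821 was -3.00 with minP and -3.59 with SV40, and rs2904163 2.15 and 2.46, while in input counts alone they were 0.47 and -2.17, and 0.67 and -0.47. The same kind of test was passed by 142 elements, of which 116 had the larger part of the difference in input, as had all 11 of those named. Among the named elements, those with a lower ratio with minP were of rs6828137 (-2.56), rs60751124 (-1.55), rs17014616 (-1.39), rs7672716 (-1.37) and rs1795734 (-1.36), and the RNA part of all 5 had the opposite direction (0.55, 0.18, 0.86, 0.11 and 0.31), with input parts of 3.11, 1.72, 2.24, 1.47 and 1.67. Those with a higher ratio with minP were rs73842243 (2.79), rs60107549 (T allele 2.55, A allele 2.53), rs2125409 (T allele 2.06, G allele 1.99) and rs13138280 (1.18). Outside the tags compared, there was also a signal: of the 1880 tags with 0 reads in both inputs, 852 had at least 10 reads in both RNA libraries, and 323 of these began with TC.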

How the results depend on the processing

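Several alternatives here, those on orientations, on RNA or input counts alone, on disjoint tags and on tags beginning with TC, were chosen after the data were seen. No paired analysis was possible because each group had 1 library. Comparison with named control elements was not run, since the table named none, and leaving out a library was not possible. Of 1038 alternative values of the 111 named differences, 946 kept their direction and side of the threshold, 89 fell short of it, 3 newly passed and 0 reversed. RNA counts alone, input counts alone and the tests on orientations were not among these values. Leaving out tags beginning with TC, few of which passed the input minimum, gave 111 of these values, and all 111 kept direction and side. In RNA counts alone, 8 called constructs with minP and 2 with SV40 had the opposite sign. Among the alternatives counted, without the split tags, 843 of 865 values kept direction and side of the threshold. In these, 6 named constructs with minP, 5 with SV40 and 0 named elements lost a call. In RNA counts alone, 16 of the 52 constructs called with minP and 22 of the 36 called with SV40 passed, in either direction. The 16 include rs7671167 in window L, orientation F, which passed there in the opposite direction. Read depth and tag number limited precision. Of the values that answer a comparison, 62 alternatives stayed within the limits set and 49 did not, as follows. The cause of these shifts was not tested, and in some of them fewer tags or constructs entered. Numbers passing with trimming lie too high, because tags were trimmed within each allele before the tests. With minP, constructs passing went from 52 to 28 with at least 30 tags, 24 and 24 in the 2 parts of the tags, 111 with trimming, 28 in RNA alone, 139 in input alone, 0 for the mean of orientations and 19 for their difference. With SV40 they went from 36 to 21, 8 and 12, 95 with trimming, 61 with summed counts, 114 in input alone, and 5 and 7 for the mean and difference of orientations. Constructs passing in both went from 29 to 17 with at least 30 tags, 46 with summed counts and 57 with trimming. Their r of 0.702 became 0.841 with at least 30 tags, 0.676 with input minimum 50, 0.675 with pseudocount 0.5, 0.757 with ranks, 0.730 with summed counts, 0.720 with trimming and 0.111 with disjoint tags. Promoter differences of the allelic difference went from 2 to 5 with input minimum 50, 11 with summed counts and 6 without tags at 0 RNA reads. Higher elements with minP went from 877 to 270 and 249 in the 2 parts and 1348 with trimming, and lower ones from 1089 to 580 and 565. With SV40, higher elements went from 950 to 287 and 272, and lower ones from 1238 to 515 and 515 and to 732 with input minimum 50. Promoter differences of elements went from 142 to 234 with input minimum 1, 88 with input minimum 50 and 270 without tags at 0 RNA reads. The r of 0.908 between promoters became 0.898 and 0.897 with input minimums 1 and 50, 0.913 with pseudocount 0.5, 0.917 with trimming, 0.866 without tags at 0 RNA reads, 0.708 with disjoint tags and 0.875 with the same part of the tags.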

Other observations

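The test on both orientations and the comparisons of levels in this part were chosen after the data were seen. With SV40, 5 windows passed when the allelic differences of their 2 orientations were averaged. The alleles were ordered alike in both orientations for rs12643428 in window R (1.31 ± 0.59 and 2.10 ± 0.48), rs12645124 in window R (-1.73 ± 0.50 and -1.63 ± 0.37), rs13124775 in window L (-2.07 ± 0.54 and -1.74 ± 0.62) and rs12645173 in window C (-1.43 ± 0.52 and -2.66 ± 0.73), each as later minus earlier allele in orientations F and RC. For rs2276936 in window R the values had opposite signs, 2.36 ± 0.23 and -0.48 ± 0.24. The adjusted p of these 5 means lay between 0.00544 and 0.00653 (permutation tests). In orientations F and RC, rs12645124 was -3.53 and -3.83 in RNA counts alone and -1.80 and -2.20 in input counts alone. In orientation F, rs13124775 was -4.51 in RNA and -2.44 in input alone, so the lower allele was also scarcer in input. Taken alone, orientation F of these 2 variants did not pass with an input minimum of 1 (adjusted p = 0.268 and 0.184, permutation tests). Nor did it without tags at 0 RNA reads. With SV40, 101 of 1633 windows had an unadjusted p under 0.05 in this test.

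RNA counts of the 2 promoters, from separate transfections, lay closer to each other than to their own inputs. Between tags of the same element, r was 0.855 for the RNA libraries, 0.582 for the inputs, 0.404 for minP RNA with its input and 0.388 for SV40 RNA with its input. Between the 2 orientations of the same allele and window, r of the element's mean level was 0.288 and 0.303 in RNA and -0.0108 and 0.0798 in input, over 3634 pairs, which are not independent.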
